A study of Rattus norvegicus with 6 samples.

How the data were processed

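The data were 6 droplet libraries from Sprague-Dawley rats: 2 of sciatic nerve from adult rats (3 months), 2 of sciatic nerve from aged rats (20 months), and 1 of dorsal root ganglion (DRG) from each age. The labels do not say that the replicates of a nerve group came from separate animals. The p-values of single genes and of class shares thus measure the spread between these samples, which may be technical. Libraries were made with a 10x Genomics single-cell 3' kit and sequenced on an Illumina instrument, per the labels' protocols. Reads were processed with Cell Ranger and cells analysed with Seurat 3.0, per the submitters' processing notes. The matrices carry a Cell Ranger header of version 4. The genome build and annotation were not given. The values are deposited counts of unique molecular identifiers (UMIs) per gene and barcode, not normalised, for 30560 genes named by their deposited symbols. They include every barcode, not called cells only. RT1 genes are near-identical paralogs among which the counting could split reads, so their values are uncertain.

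A barcode was kept as a cell with 1000 or more UMIs, 500 or more genes and at most 20% of UMIs from mitochondrially encoded genes. Doublets were scored with scrublet in scanpy 1.11.5, and the highest-scoring cells were removed at 0.8% per 1000 cells in the library. This took out 314 and 93 cells in adult nerve, 211 and 177 in aged nerve, and 449 and 37 in adult and aged DRG. The mitochondrial limit removed 0 barcodes in each nerve library, 234 in adult DRG and 17 in aged DRG. Cells of the 4 nerve libraries and of the 2 DRG libraries were clustered apart, on counts per 10000, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.8, with no batch integration (Python 3.11.15, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Clusters were called X-like from marker genes, and those led by markers of unrelated classes, with fewer than 3 leading markers, or close to free RNA stayed unnamed. The likeness to free RNA that keeps a cluster unnamed, 0.97, was set after the data were seen. It kept out DRG cluster 1, which held 1038 adult and 42 aged cells.

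Counts were summed per library and class, since cells are not replicates. Classes with 20 or more cells in each library were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood test), with Benjamini-Hochberg adjustment within a class and a threshold of 0.05 on adjusted p. The edgeR adjusted p-values printed are from that test. Log2 changes are aged over adult, with a standard error (SE) taken as the size of the log2 change over the square root of F. Levels are counts per 1e6 (CPM), given as mean and SD over 2 libraries per age. Cell numbers per class were compared with the same test over classes of 10 or more cells, with cells kept as the library size. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333 and was not used. Nerve and DRG were compared over all 6 libraries with age as a covariate. DESeq2 1.42.0 was the other tool.

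Fixed gene lists, 21 in all, were tested with camera in limma 3.58.1 (preset correlation 0.01, 5 or more genes, adjustment over all lists and classes). An estimated correlation and fry were alternatives: fry's directional p asks whether a list's genes move on balance one way, and its mixed p whether they change in either direction, and neither compares the list with other genes. The lists covered myelin and its regulators, cholesterol and fatty acid synthesis, the Schwann cell injury response, senescence, MHC class I, MHC class II, interferon response, complement, NF-kB and cytokines, collagen and matrix, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, immediate early genes, antioxidant genes, lysosome, endothelial barrier, axonal growth, nociceptor genes, cell cycle and Y-linked genes. A list of 25 splicing factor genes and a set of circadian clock genes were added after the data were seen.

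With 1 DRG library per age there is no test and no replicate check. Ratios of aged to adult CPM carry exact conditional binomial 95% intervals and shares carry exact binomial ones, and both cover counting error only. A DRG list's median log2 ratio was ranked among 10000 random lists matched on expression in 20 bins, over members with 20 or more counts and with 0.5 added to each count. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is a lower bound. Genes with 1 to 3 counts in a group are given as a ratio of summed CPM with its counting interval.

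Before the data were examined, the groups, tests, filters, markers, lists, alternatives and the rule for named genes were fixed. For the 3 largest nerve classes tested, the rule takes the 5 largest rises and 5 largest falls with edgeR adjusted p under 0.05, both aged libraries above or below both adult ones, a mean of 20 CPM or more in the higher age and an assigned symbol; where fewer pass, those with the smallest p are named as not passing. Other classes take 2 and 2. Each list called by camera adds up to 4 members with the smallest p, and 6 genes, among them Cdkn1a, Cdkn2a, Mbp, Col1a1 and Cd74, are always named. Some genes that the rule takes are not reported here. In DRG, the 3 largest named classes take 5 and 5 genes by ratio, with 50 CPM and 50 counts or more in the higher library and an interval that excludes 2-fold. The tissue comparison takes 5 and 5 in its 2 largest classes.

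Free RNA, the RNA that droplets hold without a cell, was measured as the pooled counts of barcodes with 1 to 100 UMIs in each library. Its share of a class's counts was estimated from markers of unrelated classes and subtracted as an alternative. Other alternatives were RLE factors, DESeq2, no low-count filter, doublets kept, a looser filter (500 UMIs, 300 genes), a stricter filter (2000 UMIs, 800 genes), a mitochondrial limit of 10%, thinning to the smallest library, Leiden resolutions of 0.4 and 1.2, the replicate number as a block, and leaving out each library. Added after the data were seen were a crossed pairing, tests within 1 cluster, and a free RNA profile from the plateau of barcodes below the cells. That plateau lay above 100 UMIs, at 110 and 116 in adult nerve, 256 and 276 in aged nerve, and 534 and 218 in DRG.

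The tests were tried on simulated counts with 200 changed genes drawn from the real means and library sizes. Recovered shares of 2-fold age changes were 54.1% in fibroblast-like, 37.5% in perineurial-like, 44.4% in endothelial-like, 28.1% in macrophage-like and 35.7% in myelinating Schwann-like cells. They were 6.1% in all Schwann-like and 5.1% in non-myelinating Schwann-like cells. For 4-fold changes, the shares were 89.9%, 90.9%, 89%, 84.8%, 84.2%, 76% and 58.2% in the same order. For adipocyte-like, mural-like and lymphatic-like cells, they were 19.8%, 12.9% and 6.5% at 2-fold and 78%, 81.6% and 84.2% at 4-fold. Between tissues, they were 25.5% and 79% in fibroblast-like and 27% and 86.9% in Schwann-like cells. Camera found a list changed by 1 on the log2 scale in 20 of 20 draws and called 4 of 360 others. Genes were simulated without correlation, so its preset value was not tested. The composition test found a class changed by 2 on that scale in 2 of 50 draws. The DRG intervals held a true ratio of 1, 2 and 4 in 96.67%, 96.14% and 95.40% of genes. All library pairs differed by more than counting noise (chi-square per degree of freedom 2.01 or more over 4 classes). Figures were drawn with matplotlib 3.10.9.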

Results

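The series set adult against aged rats in sciatic nerve and in DRG, which holds the cell bodies of sensory neurons with axons in that nerve. Adult nerve 1 and 2 held 33846038 and 25093652 UMIs and gave 5955 and 3309 cells. Aged nerve 1 and 2 held 39070816 and 38737306 UMIs and gave 4919 and 4528 cells. The DRG libraries held 68673369 UMIs and 7044 cells in the adult and 27426819 UMIs and 2102 cells in the aged rat. Median UMIs per cell were 2934, 3570, 2651 and 2414 in nerve and 2114 and 2230 in DRG. Barcodes with 1000 or more UMIs carried 71.3% and 57.6% of UMIs in adult nerve but 48.5% and 43.6% in aged nerve. Nerve cells carried few mitochondrially encoded UMIs, with shares of 0.0804%, 0.0499%, 0.0390% and 0.0290%, against 2.18% and 1.63% in DRG. Ribosomal protein genes took 0.236%, 0.205%, 0.247% and 0.186% of UMIs in nerve cells and 0.734% and 0.453% in DRG cells. Nuclei give such low shares, while the labels name single cells, so nerve values may be of nuclei and nerve against DRG may hold a difference in preparation. The labels name Schwann cells for nerve and neurons for DRG, while the clusters held many cell types. The labels give no preparation batch, so nerve gene differences with age may be differences in preparation.

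Fibroblast-like, Schwann-like and perineurial-like cells were the 3 largest nerve classes, with 29.1% and 39.0% fibroblast-like cells in adult nerve and 33.3% and 32.9% in aged nerve. Adipocyte-like cells took 0.772% and 1.39% of adult nerve cells and 11.7% and 6.98% of aged ones, a log2 change of 3.11 (SE 0.68) that did not pass (edgeR adjusted p = 0.0935). Macrophage-like cells took 6.15% and 10.3% against 16.5% and 12.5% (log2 0.81, SE 0.57, edgeR adjusted p = 0.549). Lymphatic-like cells took 1.11% and 0.907% against 2.36% and 1.99% (log2 1.11, SE 0.51, edgeR adjusted p = 0.432). Schwann-like cells took 30.7% and 7.13% against 6.32% and 25.5%, and perineurial-like cells 15.3% and 32.4% against 17.1% and 5.10%. Their log2 changes were -0.25 (SE 1.11) and -1.10 (SE 0.87), and those of the mural-like, muscle-like, endothelial-like and fibroblast-like classes were -1.53, 2.14, 0.28 and -0.04, all with edgeR adjusted p of 0.549 or more. Single libraries set several of these. Without adult nerve 1 the Schwann-like and mural-like classes were at 1.16 and 0.93, the muscle-like class was at 8.63 without adult nerve 2 and -0.61 without aged nerve 2, and macrophage-like cells were at 2.46 with doublets kept (edgeR adjusted p = 0.211). The edgeR quasi-likelihood test called 0 of 9 classes, with 1 at an unadjusted p under 0.05, and DESeq2 called 1, adipocyte-like cells. Shares are of captured barcodes, and the number of barcodes past the UMI minimum can set them.

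**Figure D1:**
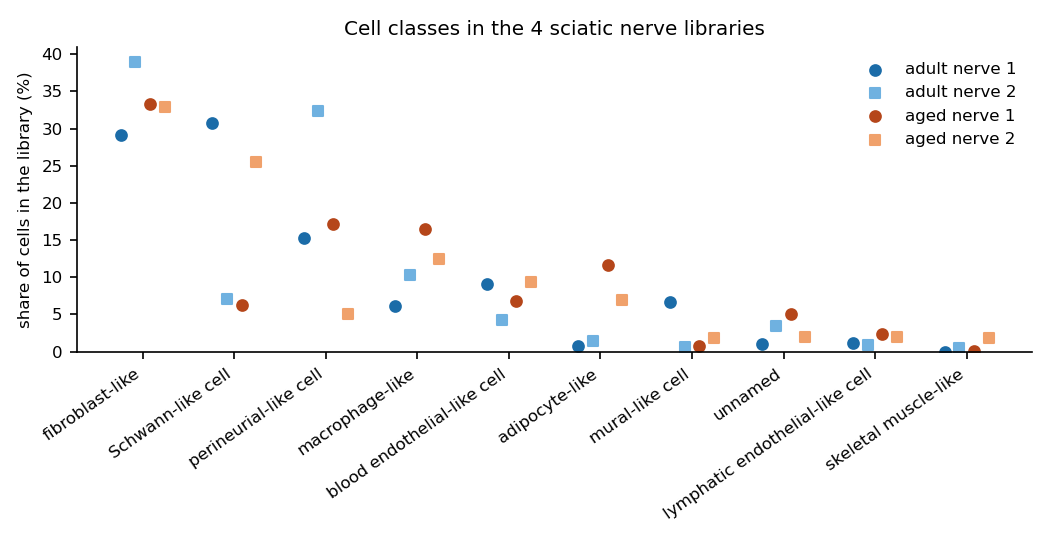
Share of cells (%) of each nerve class, 1 point per library (2 adult, 2 aged). Adipocyte-like cells lay at 0.772% and 1.39% in adult nerve and at 11.7% and 6.98% in aged nerve.

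Aged fibroblast-like cells held less Col1a1 RNA, a chain of type I collagen. It fell from 3760 CPM (SD 79.9, n = 2) to 964 CPM (SD 67.1, n = 2), a log2 change of -1.92 (SE 0.17, edgeR adjusted p = 0.00209). Of 24 collagen and matrix genes, 11 fell, among them Lum (log2 -1.83, SE 0.18), Sparc (-1.41, SE 0.15) and Col1a2 (-1.49, SE 0.16). Another 3 rose and 10 did not pass (4 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.000135, 0.608 with estimated correlation). Complement genes moved the other way. Of these, 8 of 13 rose and 0 fell (9 and 0 over the list alone). Among them were C4b (log2 2.08, SE 0.13) and C4a (2.66, SE 0.20) (camera adjusted p = 2.11e-07, 0.608 with estimated correlation). Of 16 immediate early genes, transcription factors and others that answer stimuli and tissue dissociation, 11 rose and 0 fell (14 and 0 over the list alone). Fos was at 2.85 (SE 0.38), Egr1 at 2.22 (SE 0.22) and Nr4a1 at 2.56 (SE 0.29) (camera adjusted p = 3.07e-09, 0.608 with estimated correlation). Cholesterol and fatty acid synthesis genes fell, 12 of 22 with 1 rise (14 and 1 over the list alone). They included Hmgcs1 (log2 -2.12, SE 0.23) (camera adjusted p = 6.53e-10, 0.608 with estimated correlation). Free RNA held less Col1a1 in aged nerve too, 4038 and 7860 CPM in adult and 1022 and 862 in aged libraries, and more C4b, at 216 and 417 against 693 and 693 CPM.

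In all, 3699 of 13709 genes tested in fibroblast-like cells passed the edgeR test, 1986 higher and 1713 lower with age (2368 by DESeq2). The rises named by the rule included Stmn2, which encodes a neuronal microtubule regulator, at log2 5.96 (SE 0.35, edgeR adjusted p = 0.00137), from 0.59 to 36.9 CPM. Falls included Adamts19, a secreted protease (log2 -3.32, SE 0.35), and Trmt9b (-3.01, SE 0.23). Lilrb4 and Ankef1 also rose (log2 5.19, SE 0.42 and 5.04, SE 0.46), and their free RNA levels were 17.9 and 36.8 against 310.2 and 294 CPM, and 20.3 and 31.3 against 295 and 260 CPM. Trhr and Epha7, which fell, and Fam155a, which rose, were among the 10 leading genes of clusters 0 and 14 and are not read as separate results. After free RNA was subtracted, Lilrb4 and Ankef1 had too few counts to be tested, and 1923 genes passed. Stmn2 and Col1a1 were then at 7.56 and -1.70. Smaller lists were also called, among them NF-kB and cytokine genes (6 of 14 rose and 0 fell, such as Icam1 at 1.68, 6 and 1 over the list alone; camera adjusted p = 0.0112, 0.608 with estimated correlation, 0.0515 after free RNA was subtracted). So were axonal growth genes (4 of 6 rose, 5 over the list alone; camera adjusted p = 0.0115, 0.608 with estimated correlation) and injury response genes (2 of 8 rose, Artn and Jun, 2 over the list alone; camera adjusted p = 0.0293, 0.608 with estimated correlation). Jun is in both of these lists and in the immediate early list, so the calls are not independent. Cell cycle inhibitors Cdkn1a and Cdkn2a were at log2 0.21 (SE 0.24, edgeR adjusted p = 0.54) and 0.36 (SE 0.52, edgeR adjusted p = 0.628), Cd74 at 0.11 (SE 0.31) and Mbp at 0.97 (SE 0.68).

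Different clusters held the fibroblast-like class in each age: cluster 0 held 82.2% of adult and 0.54% of aged cells, cluster 1 held 15.3% and 49.8%, and cluster 14 held 2.12% and 49.6%. Within cluster 1 alone, 1377 genes passed the edgeR test, 988 of them also called in the whole class. Collagen and matrix genes there had a median log2 change of -0.62 with 12 of 24 falling, and cholesterol and fatty acid synthesis genes -0.39 with 2 of 15 falling. Fewer fibroblast genes were called without adult nerve 1 or 2.

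Perineurial-like cells, which form the sheath around nerve fascicles, held more complement RNA in aged nerve. Of 13 complement genes, 12 rose and 0 fell (12 and 0 over the list alone). Cfd was at log2 4.66 (SE 0.35), Clu at 1.96 (SE 0.18) and C4a at 2.11 (SE 0.20). The camera adjusted p was 4.6e-09 (0.608 with estimated correlation). Free RNA held more Cfd in aged nerve, at 65.5 and 136 CPM in adult and 332 and 194 in aged libraries, and more C4a, at 148 and 269 against 397 and 468, but less Clu, at 364 and 285 against 240.2 and 129. Of 15 immediate early genes 10 rose, Jun among them (log2 1.87), and 0 fell (12 and 0 over the list alone). The camera adjusted p was 0.000451 (0.608 with estimated correlation). Of 71 ribosomal protein genes 21 rose and 1 fell (18 and 1 over the list alone; camera adjusted p = 0.0116, 0.789 with estimated correlation). That call ended without aged nerve 1 (0.21) and after free RNA was subtracted (0.22). NF-kB and cytokine genes rose in 7 of 10 cases, Icam1 and Ptgs2 (log2 2.77) among them, and fell in 0 (7 and 0 over the list alone). The camera adjusted p was 0.0158 (0.660 with estimated correlation). The NF-kB call ended without aged nerve 1 (0.179), as did the calls of Icam1 (log2 1.19, edgeR adjusted p = 0.114) and Ptgs2 (2.06, edgeR adjusted p = 0.153). The list was at 0.365 after subtraction. Lysosome genes, 8 of 17 higher and 1 lower (8 and 2 over the list alone; camera adjusted p = 0.0282, 0.608 with estimated correlation), were at 0.0857 without adult nerve 1, 0.962 after subtraction and 0.0552 with the replicate number as a block.

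In perineurial-like cells the edgeR test called 5250 of 12352 genes, 2695 higher and 2555 lower (2803 by DESeq2, 2537 after free RNA was subtracted, 2619 without aged nerve 1). Acvr1c, a receptor of the activin family, had 3 counts in adult and 49 in aged nerve, a ratio of 55.9 (95% interval 18.0 to 280.2). Ankef1 (log2 4.92, SE 0.31), Lilrb4 (4.96, SE 0.49) and Gpnmb (4.69, SE 0.39) also rose. These 4 could not be tested after subtraction. Ankef1 and Acvr1c led the adipocyte-like cluster and Lilrb4 and Gpnmb led macrophage-like cluster 17. Free RNA held 33.5 and 57.4 CPM of Gpnmb in adult and 288 and 291 in aged nerve. Falls included Rundc3b (log2 -3.96, SE 0.45), Grid1, a glutamate receptor of the delta family (-3.75, SE 0.34), Ac1576 (-3.43, SE 0.55) and Adra1b, an adrenergic receptor (-3.54, SE 0.68). Cnmd fell to a ratio of 0.0828 (95% interval 0.0168 to 0.248) while its free RNA went from 669 and 139 to 3.69 and 5.38 CPM. Its call ended without aged nerve 1 (edgeR adjusted p = 0.172) or 2 (0.0561). Cd74 was higher (0.92, SE 0.23), but not called without aged nerve 1 (0.69, edgeR adjusted p = 0.185), by DESeq2 (0.0951) or with a looser (0.578) or stricter filter (0.145). Col1a1 was at -0.40 (SE 0.17, edgeR adjusted p = 0.0723) and Mbp at 1.49 (SE 0.58, edgeR adjusted p = 0.0576). Cluster 3 held 72.3% of adult and 2.23% of aged cells of the class, cluster 11 held 26% and 1.96%, and cluster 19 held 1.66% and 95.8%.

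**Figure D2:**
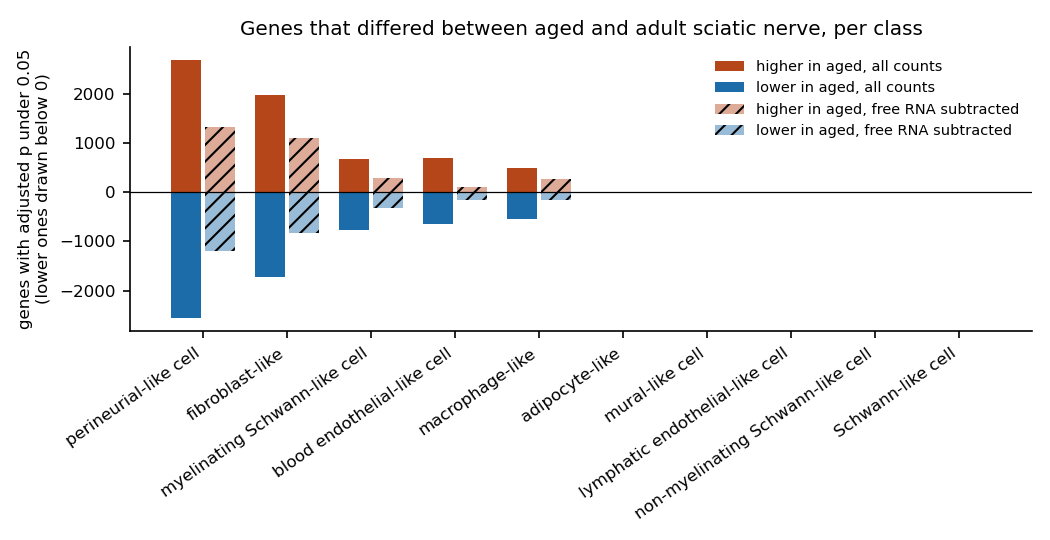
Number of genes called higher and lower with age in each nerve class by edgeR's quasi-likelihood test, from all counts (solid bars) and after free RNA was subtracted (hatched bars). Perineurial-like cells had the most calls, 2695 higher and 2555 lower from all counts.

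Myelinating Schwann-like cells of aged nerve had lower RNA of lipid synthesis enzymes and of myelin proteins. Of 22 cholesterol and fatty acid synthesis genes 20 fell and 0 rose (21 and 1 over the list alone). The median log2 change was -2.80 (camera adjusted p = 1.11e-63, 0.608 with estimated correlation). Hmgcs1, an early enzyme of the mevalonate pathway, fell from 653 to 55.6 CPM (log2 -3.56, SE 0.19, edgeR adjusted p = 4.03e-05), Idi1 by 5.74 (SE 0.35) and Cyp51 by 4.20 (SE 0.23) on the log2 scale. Free RNA of Hmgcs1 was 449 and 131 CPM in adult and 28.3 and 42.4 in aged nerve. Of 19 myelin genes 14 fell and 0 rose (16 and 1 over the list alone; camera adjusted p = 1.21e-23, 0.608 with estimated correlation). Pmp22 fell by 2.24 (SE 0.16) on the log2 scale and Mbp went from 5069 to 2518 CPM (-0.97, SE 0.14). Free RNA held 20010 and 4091 CPM of Pmp22 in adult and 342 and 762 in aged nerve. Mitochondrially encoded genes fell in 9 of 10 cases and rose in 0 (10 and 0 over the list alone). The median was -2.56 (-9.95 after subtraction), with Mt-cyb at -3.37 (SE 0.28) (camera adjusted p = 1.41e-18, 0.608 with estimated correlation).

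Of 72 ribosomal protein genes in the same cells 15 fell and 0 rose (35 and 0 over the list alone; camera adjusted p = 9.18e-11, 0.693 with estimated correlation). Among nuclear genes of oxidative phosphorylation 6 of 18 fell and 0 rose (9 and 0 over the list alone; camera adjusted p = 0.00358, 0.660 with estimated correlation, 0.168 without adult nerve 1). Complement rose in 6 of 13 genes and fell in 0 (7 and 0 over the list alone; camera adjusted p = 2.83e-06, 0.608 with estimated correlation), with C4a at log2 2.35 (SE 0.25). Injury response genes, which Schwann cells express after nerve damage, rose in 2 of 6 cases (5 and 1 over the list alone), Tnc and Shh, with a camera adjusted p of 0.0338 (adjusted p = 0.608 with estimated correlation, 0.0766 without adult nerve 1). The calls of NF-kB genes (3 of 10 higher, 3 over the list alone; camera adjusted p = 0.0436, 0.608 with estimated correlation) and MHC class I genes (2 of 8 lower, 2 over the list alone; camera adjusted p = 0.0438, 0.705 with estimated correlation) ended without single libraries. NF-kB was at 0.323, 0.0551 and 0.0611 without adult nerve 1, aged nerve 1 and aged nerve 2 and at 0.0618 with the replicate number as a block. MHC class I was at 0.0545 without aged nerve 1.

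In all, 1444 of 12562 genes passed the edgeR test in myelinating Schwann-like cells, 678 higher and 766 lower (664 by DESeq2, 622 after free RNA was subtracted). St8sia2, which adds polysialic acid to adhesion proteins, fell from 109 to 0.92 CPM (log2 -6.68, SE 0.40, edgeR adjusted p = 4.59e-05), and Lilrb4 rose (4.76, SE 0.42). Lrp1b, which rose, was among the 10 leading genes of cluster 5 and is not read as a separate result. Col1a1 was lower (log2 -0.75, SE 0.15), but was at 0.30 (edgeR adjusted p = 0.31) after subtraction and was not called without aged nerve 2 (-0.62, edgeR adjusted p = 0.129). Cd74 was at 0.28 (SE 0.37). Cluster 4 held 92.2% of adult and 1.6% of aged cells and cluster 5 held 7.85% and 98.4%, while adult nerve 2 gave 71 cells and adult nerve 1 gave 1164. Fewer genes were called without adult nerve 1 or aged nerve 2.

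**Figure D3:**
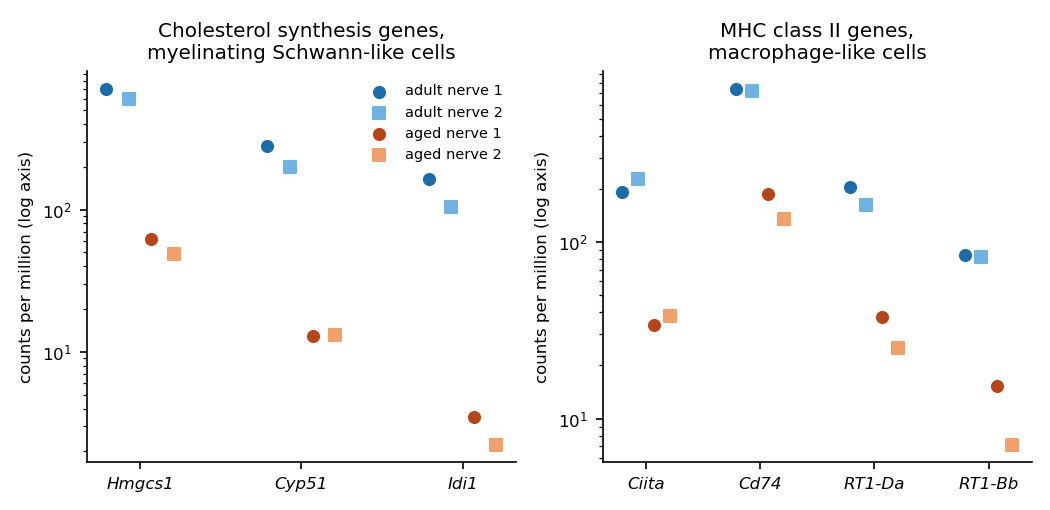
Level (CPM, log axis) per library of Hmgcs1, Cyp51 and Idi1 in myelinating Schwann-like cells and of Ciita, Cd74, RT1-Da and RT1-Bb in macrophage-like cells. In each panel both aged libraries lie below both adult libraries, for Hmgcs1 at a mean of 55.6 against 653 CPM.

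In all Schwann-like cells together, the edgeR test called 0 of 13446 genes (1866 at an unadjusted p under 0.05, 276 by DESeq2). The genes with the smallest p, none of which passed, included St8sia2 (log2 -5.89, SE 0.50, edgeR adjusted p = 0.191), the cholesterol exporter Abca1 (2.50, SE 0.21, edgeR adjusted p = 0.191), Tmem196 (3.54), Lilrb4 (4.91), Gpnmb (3.42), Myof (2.11), Aacs (-2.90), Pcsk5 (-1.90), Galnt13 (-3.33) and Fstl4 (-2.30). Mbp was at -0.59, Col1a1 at -1.08, Cd74 at 0.06 and Cdkn1a at 0.47, none passing. Lists were called all the same. Cholesterol and fatty acid synthesis fell, with a median log2 change of -2.26 and 0 of 22 genes passing over all genes (20 lower and 1 higher over the list alone; camera adjusted p = 4.18e-22, 0.608 with estimated correlation). The injury response list rose, with a median of 1.5 and 7 of 12 genes higher over the list alone and 0 over all genes. Examples were Ngfr at 2.19 and Gap43 at 2.39 (camera adjusted p = 4.34e-09, 0.608 with estimated correlation). Mitochondrially encoded genes fell (median -1.42, 5 of 12 over the list alone, 0 over all genes; camera adjusted p = 2.59e-09, 0.608 with estimated correlation). Genes were called by edgeR without adult nerve 1 or 2, but not without aged nerve 1 or 2. Myelinating cells gave 6297833 of 8040122 UMIs in adult nerve 1 but 472326 of 1543528 in adult nerve 2. This uneven mix can move genes that differ between the subtypes and widen the spread.

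Other lists called in Schwann-like cells had 0 genes passing over all genes. Upward calls were axonal growth (median log2 1.15, 4 of 7 over the list alone; camera adjusted p = 1.75e-05, 0.608 with estimated correlation, 0.0611 without adult nerve 1) and complement (0.53, 2 of 14; camera adjusted p = 0.000485, 0.730 with estimated correlation, 0.338 without adult nerve 1). NF-kB was also higher (0.45, 0 of 12; camera adjusted p = 0.0293, 0.660 with estimated correlation, 0.414 and 0.123 without adult nerve 1 and aged nerve 1). Downward calls were myelin (median -0.77, 0 of 19; camera adjusted p = 0.000275, 0.737 with estimated correlation, 0.697 without adult nerve 1) and ribosomal proteins (-0.55, 0 of 73; camera adjusted p = 2.32e-07, 0.737 with estimated correlation, 0.331 without adult nerve 1). Oxidative phosphorylation was lower too (-0.39, 0 of 18; camera adjusted p = 0.0216, 0.730 with estimated correlation, 0.8 and 0.176 without adult nerve 1 and aged nerve 2). MHC class I (-0.47, 2 of 9; camera adjusted p = 0.00707, 0.608 with estimated correlation), interferon (-0.81, 2 of 19; camera adjusted p = 0.00107, 0.608 with estimated correlation) and collagen (-0.61, 0 of 23; camera adjusted p = 0.00321, 0.693 with estimated correlation) were also called lower. These 3 and NF-kB and ribosomal proteins were no longer called after free RNA was subtracted (0.238, 0.377, 0.137, 0.421 and 0.863). MHC class I was at 0.0617 without aged nerve 2 and collagen at 0.25 without adult nerve 2. Cluster 4 held 55.1% of adult and 0.82% of aged Schwann-like cells, cluster 5 held 4.7% and 50.5%, cluster 7 held 33.1% and 47.3% and cluster 15 held 7.03% and 1.36%.

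Non-myelinating Schwann-like cells had the injury response list higher (median log2 1.38, 5 of 10 over the list alone; camera adjusted p = 4.68e-09, 0.608 with estimated correlation) and axonal growth genes higher (median 1.24, 2 of 5; camera adjusted p = 3.86e-05, 0.608 with estimated correlation). Cholesterol and fatty acid synthesis was lower (median -1.61, 0 of 20; camera adjusted p = 1.08e-07, 0.660 with estimated correlation, 0.152 without adult nerve 1), as was collagen (-0.75, 1 of 23; camera adjusted p = 2.72e-05, 0.608 with estimated correlation, 0.448 with the opposite sign after free RNA was subtracted). The edgeR test called 0 of 11259 genes (1429 at an unadjusted p under 0.05, 162 by DESeq2), with Lilrb4 at 5.14, Gpnmb at 2.84, Csrp2 at -3.76 and Nmnat2 at -1.87 (each edgeR adjusted p = 0.323). Within cluster 7 alone, which held 82.5% of adult and 97.2% of aged cells while cluster 15 held 17.5% and 2.8%, 513 genes passed. There 10 of 17 cholesterol and fatty acid synthesis genes fell and 4 of 9 injury response genes rose. Of the always-named genes, Col1a1 was at -1.37 and Cd74 at -0.05, neither passing, and Mbp was at -0.10 (edgeR adjusted p = 0.967) but at 1.45 (edgeR adjusted p = 0.000187) without adult nerve 1 and -0.79 (edgeR adjusted p = 0.0252) without adult nerve 2. Weaker list calls were complement (0.64, 3 of 12; camera adjusted p = 0.00308, 0.693 with estimated correlation), immediate early genes (0.37, 0 of 15; camera adjusted p = 0.00843, 0.608 with estimated correlation) and lysosome (0.31, 1 of 17; camera adjusted p = 0.00873, 0.660 with estimated correlation), all higher. MHC class I (-0.60, 0 of 9; camera adjusted p = 0.0218, 0.608 with estimated correlation), interferon (-0.66, 0 of 16; camera adjusted p = 0.029, 0.706 with estimated correlation) and ribosomal proteins (-0.34, 0 of 70; camera adjusted p = 0.0485, 0.903 with estimated correlation) were lower. These 6 calls ended in at least 1 fit without a library. Complement was at 0.39, MHC class I at 0.223, interferon at 0.61 and ribosomal proteins at 0.402 without adult nerve 1. Lysosome was at 0.165 without adult nerve 2, immediate early genes at 0.0569 and interferon at 0.0861 without aged nerve 1, and MHC class I at 0.097 and ribosomal proteins at 0.904 without aged nerve 2. Immediate early genes, interferon and ribosomal proteins were at 0.124, 0.497 and 0.378 after subtraction. Genes were called without adult nerve 1 or 2.

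Aged macrophage-like cells held less RNA of MHC class II, which presents antigens to helper T cells. All 8 list members fell (8 over the list alone), at a median log2 of -2.13 (camera adjusted p = 2.95e-24, 0.608 with estimated correlation). With doublets kept the median was -1.19 and 5 of 8 fell, and it was -1.50 with the stricter filter. Cd74, the invariant chain, went from 729 (SD 14.2, n = 2) to 161 CPM (SD 37.0, n = 2), a log2 change of -2.19 (SE 0.18, edgeR adjusted p = 0.0042). Ciita, the master regulator of the class, fell by 2.57 (SE 0.18), RT1-Da by 2.54 (SE 0.24) and RT1-Bb by 2.83 (SE 0.32) on the log2 scale. MHC class I fell in 5 of 9 genes (8 over the list alone) with a median of -1.27 (camera adjusted p = 2.02e-06, 0.608 with estimated correlation), but was at 0.158 after free RNA was subtracted. Interferon response fell in 6 of 18 (9 over the list alone) with a median of -0.82 (camera adjusted p = 6.99e-06, 0.608 with estimated correlation). Lysosome genes rose in 4 of 17 cases and fell in 1 (10 and 1 over the list alone). The protease Ctsd was at 3.05 (SE 0.27), Npc2 at 0.97 (SE 0.14) and Ctss lower at -0.95 (SE 0.16) but at 0.10 with doublets kept (camera adjusted p = 8.29e-06, 0.608 with estimated correlation). Immediate early genes rose in 4 of 13 cases (6 over the list alone), Nr4a1 at 2.80 among them (camera adjusted p = 5.25e-05, 0.608 with estimated correlation, 0.421 after subtraction). Injury response genes Runx2 (2.24, SE 0.19) and Artn rose among 5 (2 over the list alone; camera adjusted p = 0.034, 0.707 with estimated correlation, 0.0999 without adult nerve 1 and 0.0511 with the replicate number as a block). In free RNA Cd74 was at 467 and 704 CPM in adult and 299 and 189 in aged nerve, and B2m at 2212 and 2128 against 243 and 137.

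In macrophage-like cells 1025 of 11374 genes passed the edgeR test, 490 higher and 535 lower (779 by DESeq2). With free RNA subtracted 436 passed, 277 higher and 159 lower, so 63.5% and not 47.8% of calls were higher. Gpr143, a melanosome receptor, had 0 counts in adult and 174 in aged cells, at least 32.3-fold higher (edgeR adjusted p = 0.00766), and Tmem178a 1 and 81 counts, a ratio of 45.1 (95% interval 7.87 to 1804). Acod1, which makes itaconate in activated macrophages, had 56 and 0 counts, at least 33.5-fold lower (edgeR adjusted p = 0.00724), and Cnmd 58 and 2, a ratio of 0.0192 (95% interval 0.00227 to 0.0726). Col1a1 fell (log2 -1.25), Mbp was at -0.31 and Cdkn1a at 0.90 (SE 0.50, edgeR adjusted p = 0.281). Gpnmb, which rose, led cluster 17 and is not read as a separate result. Cluster 8 held 86.3% of adult and 20.2% of aged cells and cluster 17 held 13.7% and 79.9%. Within cluster 8, 739 genes passed, 365 of them also called in the class. The MHC class II median there was -1.22 with 5 of 8 genes falling. Lysosome genes there had a median of -0.07 (0.605 in the class), with 1 of 16 rising and 1 falling. Without aged nerve 1 the test called 20 genes and without aged nerve 2 it called 13. Ciita (log2 -2.46 and -2.66), RT1-Da (-2.87 and -2.32), Gpr143, Tmem178a, Acod1, Cnmd, Npc2, Ctss, Nr4a1, Runx2, Artn and Col1a1 were not called in either fit. Cd74 (-1.99, edgeR adjusted p = 0.053), RT1-Bb (-2.47, edgeR adjusted p = 0.053) and Ctsd (2.72, edgeR adjusted p = 0.0508) were not called without aged nerve 2.

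Aged endothelial-like cells held less RNA of MHC class I, interferon response and vessel barrier genes. Of 9 MHC class I genes 8 fell (8 over the list alone). B2m went from 872 to 163 CPM (log2 -2.43, SE 0.21, edgeR adjusted p = 0.000461). RT1-CE1 was at -2.55 (SE 0.21) and Nlrc5, which drives class I transcription, at -1.95 (SE 0.17) (camera adjusted p = 2.15e-18, 0.608 with estimated correlation). In free RNA B2m was at 2212 and 2128 CPM in adult and 243 and 137 in aged nerve. RT1-CE1 was at 362 and 334 against 38.1 and 51.1. Interferon response genes fell in 15 of 20 cases (17 over the list alone; camera adjusted p = 4.06e-16, 0.608 with estimated correlation), such as Irf1 (-1.88) and Gbp2 (-2.87). Of 11 barrier and vessel genes 9 fell (9 over the list alone; camera adjusted p = 3.31e-11, 0.608 with estimated correlation), including the glucose transporter Slc2a1 (-2.24, SE 0.28), the efflux pump Abcg2 (-2.08, SE 0.25) and Plvap (-2.18, SE 0.25). Abcg2 led cluster 10, which held 46.6% of adult and 18.0% of aged cells, while cluster 9 held 53.4% and 82.0%. Within cluster 9 alone 946 genes passed, 795 of them also called in the class. There 8 of 9 MHC class I genes and 13 of 20 interferon response genes fell, and 3 of 10 barrier genes fell.

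Ribosomal proteins fell in 22 of 71 cases (47 lower and 1 higher over the list alone; camera adjusted p = 5.52e-14, 0.608 with estimated correlation) and mitochondrially encoded genes in 8 of 12 (8 over the list alone; camera adjusted p = 3.28e-07, 0.608 with estimated correlation) in endothelial-like cells. Immediate early genes fell in 8 of 15 cases (11 lower and 1 higher over the list alone), with Btg2 at log2 -1.41. The median was -1.07 (camera adjusted p = 4.48e-05, 0.608 with estimated correlation), but -0.28 within cluster 9 alone, where 2 of 15 fell. NF-kB genes fell in 2 of 8 cases, Nfkbia and Vcam1 (4 lower and 1 higher over the list alone; camera adjusted p = 0.0218, 0.608 with estimated correlation), and were at 0.104, 0.0547 and 0.393 without adult nerve 1, adult nerve 2 and aged nerve 2. Of 5 cell cycle genes 1, Top2a, fell (1 over the list alone; camera adjusted p = 0.036, 0.608 with estimated correlation, 0.152 without aged nerve 1). The edgeR test called 1330 of 11054 genes, 695 higher and 635 lower (590.0 by DESeq2). With free RNA subtracted it called 257, of which 40.5% were higher, against 52.3% before. Klra17 had 2 and 95 counts, a ratio of 44.6 (95% interval 12.0 to 373), with free RNA of 4.89 and 23.2 against 87.2 and 74.7 CPM, and did not pass after subtraction (edgeR adjusted p = 0.0533). Pla2g2a had a ratio of 38.0 (95% interval 10.2 to 319), from 0.849 to 32.3 CPM, while its free RNA went from 21.0 and 37.7 to 185 and 102 CPM and can carry this rise, and Cnmd, with 59 and 0 counts, was at least 21.0-fold lower. Fam111a fell (log2 -6.12, SE 0.93) as its free RNA stood at 16.6 and 61.1 against 0.61 and 0 CPM. Col1a1 (-0.94), Cd74 (-0.51), Mbp (0.13) and Cdkn1a (-1.42, edgeR adjusted p = 0.0876) did not pass. None of these genes was called without aged nerve 1, where the test called 0 genes (1940.0 at an unadjusted p under 0.05, with DESeq2 run on all 4 libraries only), and the number was 138 without aged nerve 2 and 446 without adult nerve 1, where 37.9% were higher.

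Adipocyte-like cells of aged nerve had lower RNA of fatty acid synthesis enzymes. Acaca, acetyl-CoA carboxylase, fell from 3124 (SD 19.3, n = 2) to 200.1 CPM (SD 4.76, n = 2), a log2 change of -4.06 (SE 0.21, edgeR adjusted p = 0.00125). Elovl6, a fatty acid elongase, fell by 4.27 (SE 0.33), and Pnpla3, a lipase relative, by 4.29 on the log2 scale. The cholesterol and fatty acid synthesis list fell (camera adjusted p = 5.05e-24, 0.608 with estimated correlation). In it 3 of 17 genes fell over all genes and 8 over the list alone. Grb14, an adapter of the insulin receptor, rose (log2 3.71, SE 0.35, edgeR adjusted p = 0.0162), and Nav2 was at 2.52 (edgeR adjusted p = 0.062). The edgeR test called 11 of 10238 genes, 1 higher and 10 lower (79 by DESeq2). It called 0 without aged nerve 2 (356 at an unadjusted p under 0.05), where Acaca was at -4.04 (edgeR adjusted p = 0.254), and 34 without adult nerve 1 or aged nerve 1. MHC class I (median -1.45, 4 of 6 lower over the list alone; camera adjusted p = 7.69e-07, 0.608 with estimated correlation) and interferon (-0.95, 0 of 13; camera adjusted p = 0.000562, 0.707 with estimated correlation) were called lower. So were collagen (-0.28, 0 of 22; camera adjusted p = 0.00398, 0.608 with estimated correlation) and myelin (-0.82, 2 of 11; camera adjusted p = 0.00969, 0.737 with estimated correlation). Mitochondrially encoded genes (-0.82, 0 of 8; camera adjusted p = 0.017, 0.707 with estimated correlation) and ribosomal proteins (-0.37, 0 of 66; camera adjusted p = 0.0223, 0.793 with estimated correlation) were lower too. Without adult nerve 1, interferon was at 0.265, collagen at 0.222, myelin at 0.883 and mitochondrially encoded genes at 0.338. Ribosomal proteins were at 0.357 without adult nerve 2 and 0.0515 without aged nerve 1, where mitochondrially encoded genes were at 0.0661. Without aged nerve 2 interferon was at 0.0682, collagen at 0.203, mitochondrially encoded genes at 0.481 and ribosomal proteins at 0.458. Grb14 was at an edgeR adjusted p of 0.0555 and 0.0972 without adult nerve 1 and adult nerve 2 and 0.0609 with doublets kept, and Pnpla3 at 0.0883 with doublets kept and 0.0652 after free RNA was subtracted. Adult libraries gave 46 adipocyte-like cells each, and Col1a1 (-1.52), Cd74 (0.60) and Mbp (-0.54) did not pass.

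In mural-like cells 1 of 5746 genes passed the edgeR test (466 at an unadjusted p under 0.05, 3 by DESeq2), Pde10a, a phosphodiesterase, higher at log2 3.43 (SE 0.38, edgeR adjusted p = 0.0209). It was at 0.169 after free RNA was subtracted and 0.134 with the replicate number as a block, and 50 to 95 genes passed when single libraries were left out. Ptcd3 (3.00, edgeR adjusted p = 0.0594), RT1-T24-1 (-1.84), Ubb (-2.48), Col1a1 (-1.57), Cd74 (-0.04), Mbp (-0.09) and Cdkn1a (0.09) did not pass. Complement was called higher (median 1.08, 3 higher and 1 lower of 6 over the list alone; camera adjusted p = 0.0435, 0.707 with estimated correlation, 0.19 and 0.563 without adult nerve 1 and aged nerve 1). Collagen was called lower (-0.38, 7 lower and 1 higher of 22; camera adjusted p = 0.00321, 0.608 with estimated correlation, 0.652 with the opposite sign after subtraction). In lymphatic-like cells 0 of 5651 genes passed (795 at an unadjusted p under 0.05, 22 by DESeq2). Vegfa was at 2.48 (edgeR adjusted p = 0.132), Insyn2a at -2.70 and RT1-T24-1 at -1.70. Col1a1 (-0.73), Cd74 (1.04) and Mbp (0.74) did not pass either. Mitochondrially encoded genes were called lower (median -1.83, 8 of 8 over the list alone; camera adjusted p = 2.14e-12, 0.608 with estimated correlation) and complement higher (1.14, 2 of 8; camera adjusted p = 0.000555, 0.608 with estimated correlation, 0.0937 without aged nerve 1). MHC class I was lower (-0.62, 2 of 6; camera adjusted p = 0.0113, 0.608 with estimated correlation, 0.132 without aged nerve 2). Collagen was higher (0.41, 5 higher and 1 lower of 20; camera adjusted p = 0.0293, 0.660 with estimated correlation, 0.104, 0.116 and 0.27 without adult nerve 1, adult nerve 2 and aged nerve 1). Lymphatic genes were called without adult nerve 1 or 2, and the 2 adult libraries gave 66 and 30 lymphatic-like cells.

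Over all nerve classes, camera called 70 of 164 tests of fixed lists, 28 higher and 42 lower. With estimated correlation it called 0 (12 at an unadjusted p under 0.05, smallest adjusted p = 0.608). Fry called 0 (33 at an unadjusted directional p under 0.05, 90 at a mixed p under 0.05). With free RNA subtracted 52 of 128 tests were called. Senescence and antioxidant lists were called in no class, and the nociceptor and Y-linked lists had too few genes to be tested in nerve. Median, mean and test direction of a list differed in sign in 12 tests, none of them called, such as complement in macrophage-like and interferon response in perineurial-like cells. Differences in effect between classes were not tested.

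**Figure D4:**
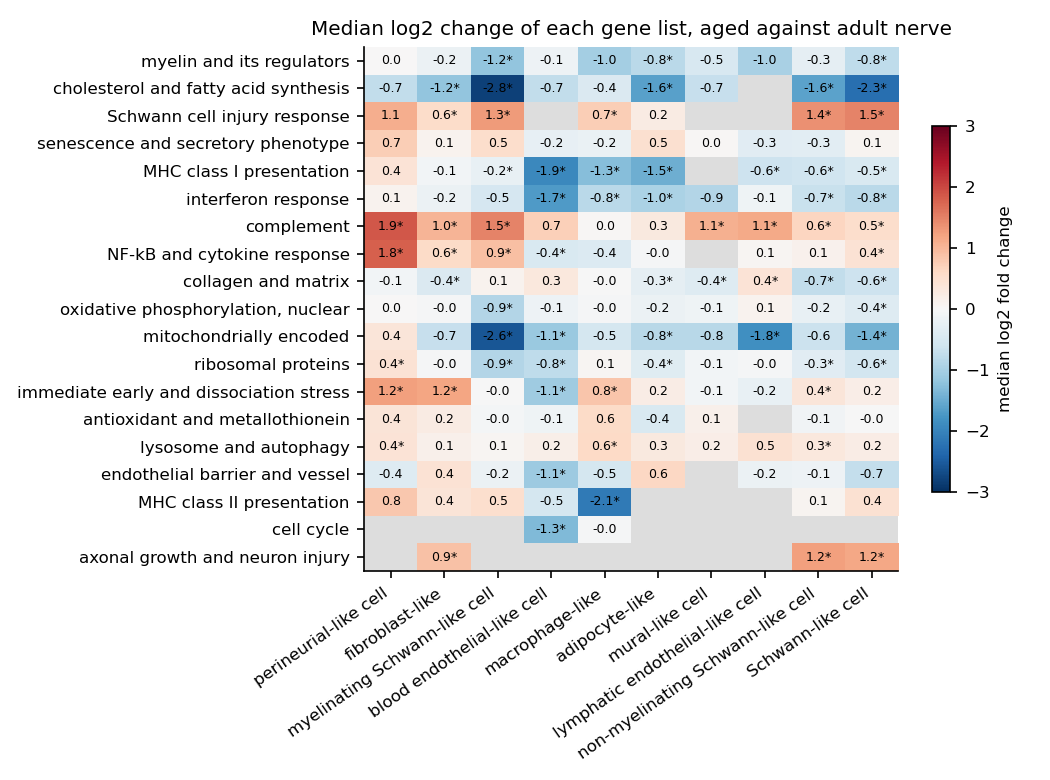
Median log2 change (aged over adult) of each fixed list in each nerve class, with colour limited to 3 on either side, an asterisk where camera's adjusted p was under 0.05 and grey where fewer than 5 genes were tested. Cholesterol and fatty acid synthesis in myelinating Schwann-like cells has a median of -2.80.

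In fibroblast-like and Schwann-like cells, the named genes higher in DRG than in nerve were genes of neurons, at levels below those in DRG free RNA. In fibroblast-like cells, Calca, the CGRP precursor of sensory neurons, had 2287 counts in DRG and 0 in nerve, at least 9461-fold higher (edgeR adjusted p = 0.000438), at 1502 and 703 CPM in the adult and aged DRG. Nefm, a neurofilament, was at log2 -11.43 in nerve over DRG (SE 0.60, edgeR adjusted p = 0.000125). Nefl, Tac1 and Nefh had 1, 1 and 2 counts in nerve, with ratios of DRG over nerve of 20900.0 (95% interval 3746 to 825970.0), 14012 (2510 to 553920.0) and 10332 (2856 to 85384). DRG free RNA held 4293 and 3409 CPM of Calca and 2463 and 1712 CPM of Nefh in the adult and aged library. After subtraction Nefm (log2 -11.11, edgeR adjusted p = 0.00742) and Tac1 (-9.38, edgeR adjusted p = 0.00751) kept their calls, and Calca, Nefl and Nefh were not tested. Higher in nerve were Hoxc11, a developmental regulator of position (log2 4.74, SE 0.52, edgeR adjusted p = 0.00251), Dkk2 (4.05, SE 0.52) and Cmahp (4.74, SE 0.79), Lpl at a ratio of 33.6 (95% interval 9.26 to 278) and Mettl11b at 35.9 (95% interval 6.40 to 1419). Hoxc11 kept its call after free RNA was subtracted, where Dkk2 was at an edgeR adjusted p of 0.0564, Mettl11b at 0.0564, Cmahp at 0.0632 and Lpl at 0.148. In Schwann-like cells, Nefh, Tac1, Pcp4 and Calcb had 0 counts in nerve. They were at least 4077-fold, 2673-fold, 650.9-fold and 327-fold higher in DRG, and Calca had a ratio of 16438 (95% interval 2948 to 649460.0). After subtraction Tac1 was not called (edgeR adjusted p = 0.504) and the other 4 were not tested. Ankef1 was at least 26-fold higher in nerve, Dnah11 was at log2 6.43 (SE 0.73), Egfr at 5.78 (SE 0.90), Dkk2 at a ratio of 90.5 (95% interval 16.2 to 3584) and Esr1, an estrogen receptor, at 54.5 (95% interval 9.69 to 2160.3). After subtraction Dnah11, Egfr, Dkk2 and Esr1 were not called (edgeR adjusted p = 0.526, 0.504, 0.549 and 0.549) and Ankef1 was not tested. Nerve free RNA held more Ankef1 (20.3 to 295 CPM), Dkk2 (47.9 to 59.2) and Esr1 (29.1 to 58.4) than these cells.

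The edgeR test over 6 libraries called 1865 of 14477 genes in fibroblast-like cells, 474 higher in nerve and 1391 in DRG, and 578 of 12649 in Schwann-like cells, 81 and 497. In macrophage-like, endothelial-like and mural-like cells it called 1779, 1544 and 239 genes, 667, 505 and 29 of them higher in nerve. After free RNA was subtracted it called 222, 505 and 1 in these classes and 135 in fibroblast-like cells. In Schwann-like cells it called 0 (882 at an unadjusted p under 0.05, 1268 by DESeq2 on all counts). The share higher in nerve went from 25.4% to 43.0% in fibroblast-like, 37.5% to 64.9% in macrophage-like and 32.7% to 49.9% in endothelial-like cells. With 1 DRG library per age the test leans on single libraries. Without adult DRG 276 genes were called in fibroblast-like, 355 in macrophage-like, 23 in mural-like and 1 in Schwann-like cells. The calls of all 10 named Schwann genes and of Cmahp and Mettl11b in fibroblast-like cells ended.

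In DRG, sensory neuron-like cells of the aged library held more ribosomal protein RNA. The median log2 ratio was 0.45, with 70 of 76 genes above 0, at percentile 100 of matched random lists. Percentiles rank lists within 1 library per age and do not test age. Among single genes Rpl39 had a ratio of aged over adult CPM of 6.31 (95% interval 5.16 to 7.73), Rps25 of 5.43 (4.54 to 6.51) and the elongation factor Eef1b2 of 4.07 (3.53 to 4.69). Immediate early genes (median 0.75, 13 of 16 above 0, percentile 100) and axonal growth genes (0.66, 9 of 11 above 0, percentile 99.99) were also higher. Nociceptor genes, of pain-sensing neurons, were at 0.07 (7 of 13 above 0, percentile 82.6). Lower were Apoe at 0.123 (0.110 to 0.136), Sparc at 0.177 (0.115 to 0.260), Ptgds at 0.228 (0.166 to 0.307) and RT1-CE1 at 0.231 (0.163 to 0.318), genes of glia and other cells. Cd74 had 3 counts in aged neuron-like cells, a ratio of 0.0416 (0.00853 to 0.123). DRG free RNA held 10108 and 2675 CPM of Apoe in the adult and aged library. Mitochondrially encoded genes were at 0.15 (percentile 98.5) and MHC class I, interferon and complement at -1.71, -1.42 and -1.26. Mbp was at a ratio of 0.733, Col1a1 at 0.114, Cdkn2a at 1.64 (0.812 to 3.15) and Cdkn1a at 0.387 (0.0756 to 1.24). Cluster 14 held 46.1% of 714 adult and 30.4% of 92 aged neuron-like cells.

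DRG Schwann-like cells of the aged library had lower RNA of MHC class I (median log2 ratio -2.71), MHC class II (-3.33), interferon response (-2.73) and complement (-1.89). Satellite glia-like cells, which wrap the neuron bodies, had -2.46, -2.54, -2.58 and -1.46. Mx1, an interferon-induced antiviral protein, was at a ratio of 0.0589 (95% interval 0.0232 to 0.126) in Schwann-like cells and, with 1 aged count, at 0.0134 (0.000337 to 0.0751) in satellite glia-like cells. RT1-CE1 was at 0.0794 (0.0489 to 0.123) and Nmnat2, an enzyme that sustains axons, at 0.0813 (0.0604 to 0.107) in Schwann-like cells. Satellite glia-like cells had Tap1 at 0.0540 (0.0110 to 0.16), Gbp2 at 0.0676 (0.0217 to 0.16) and Nwd2 at 0.00935 (0.00193 to 0.0274). Free RNA of RT1-CE1 was 375 CPM in adult and 65.3 in aged DRG. Estimated free RNA took 35.6% of adult and 14.1% of aged counts in Schwann-like and 24.6% and 10.9% in satellite glia-like cells. Mpo, a granule enzyme that led the neutrophil-like cluster, was at 38.3 (16.2 to 119) and 57.8 (21.6 to 218) in the 2 classes while its free RNA went from 17.0 to 1008 CPM. Higher in aged Schwann-like cells were Lrp1b at 8.09 (6.48 to 10.2) and Spon1 at 7.4 (4.78 to 12.0). In satellite glia-like cells they were Caln1 at 33.5 (16.2 to 80.3), Sorcs3 at 6.91 (5.95 to 8.03), Dcc, an axon guidance receptor, at 6.30 (5.45 to 7.30) and the clock gene Per2 at 5.33 (3.51 to 8.17). Cholesterol and fatty acid synthesis was at -1.11 in Schwann-like, -0.34 in satellite glia-like and -0.22 in neuron-like cells, and myelin at -0.27, -0.30 and -0.53.

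The other lists, in Schwann-like, satellite glia-like and neuron-like DRG cells in that order, had median log2 ratios of -1.57, -1.24 and -0.23 for oxidative phosphorylation, -0.54, -0.70 and -1.09 for collagen, -0.04, -1.26 and -0.37 for injury response. They were -0.12, -0.13 and -0.70 for senescence, 0.15, -0.42 and 0.21 for NF-kB, -0.63, -0.73 and 0.05 for lysosome, -0.61, -0.38 and -0.04 for antioxidant genes and -0.02, -0.22 and -0.10 for endothelial barrier genes. Ribosomal proteins were at -1.42 and -1.18, mitochondrially encoded genes at -1.84 and -1.40, immediate early genes at -0.67 and -0.94, axonal growth genes at -0.67 and -1.42 and nociceptor genes at -1.51 and -1.37 in Schwann-like and satellite glia-like cells. MHC class II was at -1.47 and cell cycle at -0.88 in neuron-like cells. Mbp was at a ratio of 0.853, Col1a1 at 0.691, Cd74 at 0.0972 and Cdkn1a at 0.187 (0.0347 to 0.661) in Schwann-like cells, where Cdkn2a had 0 adult and 4 aged counts. In satellite glia-like cells Mbp was at 1.2, Col1a1 at 0.398 (1.56 after free RNA was subtracted) and Cd74 at 0.130. Schwann-like cells took 10.1% of adult and 28% of aged DRG cells (ratio 2.77, 95% interval 2.48 to 3.10, but 9.02 with the looser filter), satellite glia-like 11.8% and 10.2% (0.870, 0.745 to 1.01), neuron-like 10.1% and 4.38% (0.432, 0.344 to 0.537). Endothelial-like cells took 3.22% and 12.0% and neutrophil-like cells 1.43% and 8.09%. Unnamed clusters took 46.3% of adult and 22.8% of aged cells, and a cluster mostly of 1 library may be that library and not a cell type.

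**Figure D5:**
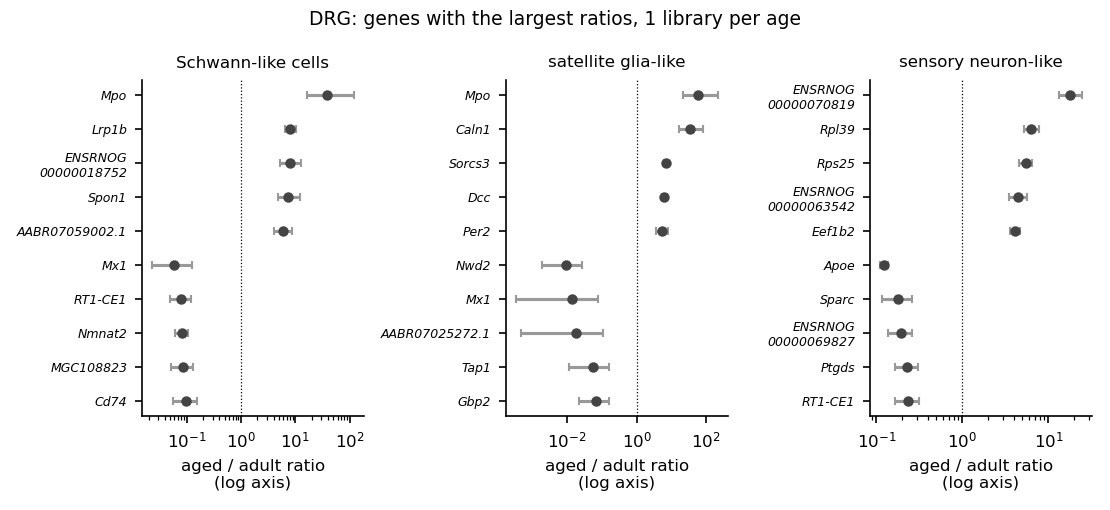
Ratio of aged over adult CPM (log axis) of named genes in 3 DRG classes, with 1 library per age and bars for exact 95% counting intervals. In neuron-like cells Rpl39 lies at 6.31 and Apoe at 0.123.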

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

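The tests of less cytoplasmic RNA and of free RNA as the whole cause in fibroblast-like and perineurial-like cells were chosen only after the result was seen. Some genes moved 1 way in nerve and the other way in DRG, and these differences between tissues were not tested. Stmn2 in fibroblast-like cells rose with age in nerve (log2 5.96, SE 0.35) and had a ratio of 0.255 in DRG (95% counting interval 0.205 to 0.313, 1553 adult and 95 aged counts). The DRG levels of Stmn2, 1199.7 and 306 CPM, lay below the 3302 and 2146 CPM of DRG free RNA, so that ratio can follow free RNA and is not read as a change in fibroblast-like cells. In endothelial-like cells Abcg2 fell in nerve (-2.08, SE 0.25) and was at 1.55 in DRG (1.40 to 1.70), Slc2a1 fell (-2.24, SE 0.28) and was at 1.33 (1.17 to 1.5), and Flt1 fell (-1.10, SE 0.14) and was at 1.15 (1.08 to 1.24). Without aged nerve 1 none of these 3 was called in nerve, at an edgeR adjusted p of 0.186 each. Srebf2 in fibroblast-like cells fell in nerve (-1.50, SE 0.12) and was at 1.36 in DRG (1.05 to 1.75), and C4a in myelinating Schwann-like cells rose in nerve (2.35, SE 0.25) and was at 0.402 in DRG (0.244 to 0.646). DRG free RNA held 228 and 167 CPM of C4a, against 49.8 and 20.0 in the cells, so its ratio too can follow free RNA.

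In each of 5 nerve classes (fibroblast-like, perineurial-like, endothelial-like, macrophage-like and myelinating Schwann-like), 76 of 10063 genes were called higher with age, against 0.0558 if the classes were independent, and 17 lower, against 0.0369, though the classes came from the same 4 libraries. In 85.5% of gene, class and library sets the level in aged cells was at or below that in the library's free RNA. This fits free RNA as an explanation. With free RNA subtracted, 1 gene stayed called in all 5 classes and 8 in none. In fibroblast-like and perineurial-like cells 46 of 76 stayed called in each (60.5%), which argues against free RNA as the whole cause in these 2 classes. The median log2 change of the genes still tested went from 1.37 (quartiles 0.93 and 2.07) to 1.07 (0.72 and 2.14) in fibroblast-like and from 1.81 (1.46 and 2.49) to 1.74 (1.27 and 2.63) in perineurial-like cells. In endothelial-like, macrophage-like and myelinating Schwann-like cells 6, 23 and 12 stayed called, and the medians went from 1.18 (0.96 and 2.23) to 0.51 (0.02 and 1.14), from 1.53 (0.95 and 2.67) to 1.25 (0.52 and 3.04) and from 1.32 (0.92 and 2.34) to 0.80 (0.38 and 1.67). Part of the calls ended as 14, 18, 30, 18 and 28 of the genes had too few counts left to be tested in the 5 classes in this order. The genes called in all 5 classes were 16, 60, 0 and 2 without adult nerve 1, adult nerve 2, aged nerve 1 and aged nerve 2, so the joint call hardly depended on adult nerve 2 and ended for most genes without any other library. The median kept at least 86.3% of its value in every class in these fits, but the genes had been picked by their calls in the same libraries, which fixes much of that outcome, so a single library as the cause cannot be told apart from a change in both libraries of an age. Age and a difference in preparation between the ages stay open and untested.

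In myelinating Schwann-like cells the median log2 change of cholesterol and fatty acid synthesis genes was -2.80. It was -2.75 after free RNA was subtracted and -2.59 or lower without any 1 library, which argues against both as the whole cause. Less cytoplasmic RNA in the aged cells cannot be told apart from a fall of the list itself. Mitochondrially encoded genes had a median of -2.56 (a difference of -0.25), but -9.95 after subtraction, so their aged level can be free RNA. Ribosomal protein genes had -0.89 (a difference of -1.92). Make-up by cluster could not be tested, as a library had 7 cells in cluster 5. That aged cells may make less lipid is a hypothesis for lipid measurements to test, with age and preparation confounded.

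The fall of MHC class II genes in macrophage-like cells (median log2 -2.13) was -2.28 after free RNA was subtracted and -1.88 or lower without any 1 library, which argues against both as the whole cause, though 3 and 0 of the 8 genes were called without aged nerve 1 and 2. It was -1.19 with doublets kept (5 of 8 genes called lower) and -1.50 with the stricter filter. Within cluster 8, held by all 4 libraries, the median was -1.22 with 8 of 8 genes below 0, which argues against a change in the make-up of the class by cluster as the whole cause. Age and a difference in preparation stay open and untested.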

How the results depend on the processing

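The plateau profile, the fits within 1 cluster and the crossed pairing were chosen after seeing the data. Of 6123 values of reported age genes under alternatives, 4996 kept their direction and side of the threshold, 696 passed only under the alternative, 354 no longer passed, 11 turned and 66 that never passed changed sign. Of 682 list results 428 were the same, 243 no longer passed and 11 turned. Of 299 values of named tissue genes 261 were the same and 38 no longer passed. Of 117 shares 108 were the same, 8 moved and 1 passed only under the alternative, and of 91 DRG ratios 73 were the same, 17 moved and 1 turned, with Cdkn2a in Schwann-like cells left out for its 0 adult counts. Of 183 age gene counts 97 lay within 1.5 times, and of 78 tissue gene counts 30 did. RLE size factors moved no age gene count past 1.5 times. The mitochondrial limit of 10% removed no nerve cell, as the highest share there was 9.53%, so its nerve values, 381 of the age gene values among them, repeat the main fit and test nothing. The stricter filter left 19 mural-like cells in a library for age and 0 macrophage-like and 11 mural-like cells for tissue, so these were not run, and the looser filter left no named satellite glia or sensory neuron cluster. Where a library was left out, the lone library of an age was assumed to vary like the others. Causes were not tested unless a setting's own construction gives them, such as fewer counts after thinning.

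Age genes called were as follows. With DESeq2 there were 276 in Schwann-like, 79 in adipocyte-like, 590.0 in endothelial-like, 2368 in fibroblast-like, 22 in lymphatic-like, 3 in mural-like, 664 in myelinating, 162 in non-myelinating and 2803 in perineurial-like cells. With no low-count filter there were 1201 in Schwann-like, 617 in adipocyte-like, 2108 in endothelial-like, 250.0 in lymphatic-like, 2199 in macrophage-like, 81 in mural-like, 2331 in myelinating and 889 in non-myelinating cells. With doublets kept there were 1228 in Schwann-like, 6 in adipocyte-like, 9 in lymphatic-like and 424 in non-myelinating cells. After free RNA was subtracted there were 257 in endothelial-like, 1923 in fibroblast-like, 4 in lymphatic-like, 436 in macrophage-like, 622 in myelinating and 2537 in perineurial-like cells. With the plateau profile there were 18 in adipocyte-like, 87 in endothelial-like (25.3% higher), 495 in macrophage-like, 0 in mural-like (216 at an unadjusted edgeR p under 0.05, 3 by DESeq2 on all counts) and 600.0 in myelinating cells. The looser filter gave 719 in Schwann-like, 20.0 in adipocyte-like, 4 in lymphatic-like, 2310.0 in macrophage-like and 12 in non-myelinating cells. The stricter filter gave 773 in Schwann-like, 6 in adipocyte-like, 2386 in fibroblast-like, 39 in lymphatic-like, 153 in non-myelinating and 2885 in perineurial-like cells. Thinning to the smallest library gave 32 in adipocyte-like, 834 in endothelial-like, 6 in lymphatic-like, 3 in mural-like, 664 in myelinating and 2585 in perineurial-like cells. Leiden resolution 0.4 gave 989 in Schwann-like, 12 in mural-like and 160.0 in non-myelinating cells, and 1.2 gave 1799 in Schwann-like, 1843 in macrophage-like and 576 in non-myelinating cells. Within 1 cluster there were 1377 in fibroblast-like and 513 in non-myelinating cells. Without single libraries the counts ranged from 0 to 1667 in Schwann-like, 0 to 34 in adipocyte-like, 0 to 1570.0 in endothelial-like, 1491 to 3867 in fibroblast-like, 0 to 292 in lymphatic-like, 13 to 1340.0 in macrophage-like, 50 to 95 in mural-like, 521 to 1819 in myelinating, 0 to 1638 in non-myelinating and 2619 to 4545 in perineurial-like cells.

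The replicate number as a block gave 87 age genes in adipocyte-like and 4 in lymphatic-like cells. Other counts stayed within 1.5 times, such as 3993 in fibroblast-like and 5519 in perineurial-like cells. The labels do not say that equal numbers pair the libraries, and the changes of 2 such pairs had a correlation of -0.253 to 0.101 over the classes. With the pairing crossed, edgeR called 4 in Schwann-like, 132 in adipocyte-like, 126 in mural-like and 469 in myelinating cells.

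Tissue genes called were 1268 in Schwann-like cells with DESeq2. No low-count filter gave 2364 in Schwann-like, 2486 in endothelial-like, 3443 in fibroblast-like, 2919 in macrophage-like and 653 in mural-like cells, and doublets kept 1669 in Schwann-like, 3354 in fibroblast-like and 2878 in macrophage-like cells. After free RNA was subtracted edgeR called 0 in Schwann-like (882 at an unadjusted p under 0.05, 1268 by DESeq2 on all counts), 505 in endothelial-like, 135 in fibroblast-like, 222 in macrophage-like and 1 in mural-like cells, and with the plateau profile 1, 541, 209, 109 and 0 (324 at an unadjusted p under 0.05 in mural-like cells). The looser filter gave 1424 in Schwann-like cells, the stricter one 942 in Schwann-like, 755 in endothelial-like and 3742 in fibroblast-like cells, the 10% mitochondrial limit 919 in Schwann-like and 3085 in fibroblast-like cells, and thinning 566 in fibroblast-like, 769 in macrophage-like and 87 in mural-like cells. Without single libraries they ranged from 1 to 1251 in Schwann-like, 923 to 1876 in endothelial-like, 276 to 4391 in fibroblast-like, 355 to 2258 in macrophage-like and 23 to 346 in mural-like cells. The share higher in nerve in Schwann-like cells was 14.0% and went to 37.3% with DESeq2 and 40.1% with no low-count filter.

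DESeq2 called 1 class share, and of the lists camera with an estimated correlation and fry called 0 (12 and 33 at an unadjusted p under 0.05). The DRG share ratio of aged over adult was 9.02 for Schwann-like cells with the looser filter and 0.669 for satellite glia-like cells with the stricter one. After free RNA was subtracted the log2 change turned for Hnrnph1 in endothelial-like (-0.82), macrophage-like (-0.93) and myelinating cells (-0.13), B2m in macrophage-like (9.51) and myelinating cells (1.24), Col1a1 in myelinating cells (0.30) and Ctsd in perineurial-like cells (-7.10), and the Col1a1 ratio in DRG satellite glia-like cells was 1.56. With the plateau profile it turned for B2m in macrophage-like (8.20) and Col1a1 in myelinating cells (0.59), with doublets kept for Ctss in macrophage-like cells (0.10), and without adult nerve 1 for Mbp in non-myelinating cells (1.45, within a range of -0.79 to 1.45 over the left-out libraries). Lists that turned, with the camera adjusted p of the turned direction, were MHC class I (0.238) and collagen (0.137) in Schwann-like, collagen (0.652) and splicing (0.724) in mural-like and collagen (0.448), ribosomal proteins (0.378) and splicing (0.724) in non-myelinating cells after free RNA was subtracted. With the plateau profile NF-kB in Schwann-like (0.901) and ribosomal proteins in non-myelinating cells (0.141) turned, and ribosomal proteins in non-myelinating cells also without adult nerve 1 (0.402) or aged nerve 2 (0.904), with a range of 7.89e-07 to 0.904 over the left-out libraries.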

Other observations

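The splicing factor list and the clock gene list were chosen only after the result was seen. Transcripts of 25 splicing factors, which process messenger RNA precursors, had median log2 changes of 0.08 to 0.80 with age in 10 of 10 nerve classes and were called higher in 9 (camera adjusted p from 2.61e-06 to 0.0528, adjusted p = 0.328 to 0.333 with an estimated correlation). In perineurial-like cells 15 rose. After free RNA was subtracted the list was still called in fibroblast-like (camera adjusted p = 0.00106) and perineurial-like cells (5.13e-09), and no longer in endothelial-like (0.405), macrophage-like (0.502), myelinating Schwann-like (0.136), lymphatic-like (0.218) or all Schwann-like cells (0.32), and in mural-like and non-myelinating cells it turned (0.724 each). It was at 0.0721 in Schwann-like, 0.0885 in mural-like and 0.0917 in non-myelinating cells without aged nerve 2, and at 0.0729 in non-myelinating cells without adult nerve 1. Free RNA of Hnrnph1 was 649 and 886 CPM in adult and 1829 and 1777 CPM in aged nerve.

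Some clock genes were higher in aged nerve and others lower, with no test of the group. Dbp, an output of the circadian clock, had log2 changes of 1.09 to 2.72 in 10 of 10 classes (5 called), Nr1d1 of 0.69 to 3.03 in 10 of 10 (5 called) and Per2 of 0.63 to 2.72 in 10 of 10 (4 called). Free RNA of Per2 was 29.8 and 79.1 CPM in adult and 187 and 271 in aged nerve. Arntl, a core activator of the clock, was below 0 in 9 of 9 classes (-2.07 to -0.64, 4 called) and Npas2 in 10 of 10 (-2.54 to -0.36, 2 called). Nr1d2, Per1 and Per3, above 0 in 9 of 10, 7 of 8 and 7 of 10 classes, were called in 0, and Tef, Hlf and Cry1, above 0 in 5 of 10, 4 of 8 and 6 of 8, in 1 each. In DRG the ratio of Dbp was 2.59 in Schwann-like, 3.99 in satellite glia-like and 1.48 (95% interval 0.876 to 2.44) in neuron-like cells, and that of Arntl 0.651, 0.303 and 0.501. Other DRG ratios went the other way, with Per3 at 0.737 (95% interval 0.584 to 0.920) in neuron-like cells, or had intervals that held 1, with Npas2 at 2.08 (0.904 to 5.18) in Schwann-like cells, Bhlhe41 at 0.975 and 0.757 in Schwann-like and satellite glia-like cells and Clock at 0.930 to 1.16 in all 3. The labels give no collection time.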
